A study of Mus musculus with 9 samples.

How the data were processed

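RNA sequencing of 9 mouse samples was used: CT26 cells with Pd-l1 knocked out and then given an empty retroviral vector (KO), wild-type Pd-l1 (WT) or K262Q Pd-l1 (K262Q), 3 samples each. Per the labels, the cells were grown in RPMI with FBS and selected with puromycin, total RNA was isolated with Trizol, and the authors aligned reads to mm10 with STAR 2.5.4a and quantified genes with Cufflinks 2.2.1 and Cuffdiff. The deposited table gives 1 FPKM value per gene and sample; it holds no read counts and the strand is not stated. All 9 sample columns were used.

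Genes were joined by Ensembl ID to GENCODE mouse release 21 (GRCm38) for positions, biotypes and transcript lengths: 53702 of 53796 genes had a record, and for 97.7% of these it lay inside the locus in the table. Depth was inferred from the steps between low values of 5353 genes with 1 transcript. There 77.0% of values above the smallest of their gene lay within 0.03 of a whole multiple of it. Evenly spread values would give 6.0%. Values of 1 fragment in other libraries can count among the 77.0%, and the steps were set on these same genes. The 6.0% is therefore no strict chance rate. The implied depth was 17.9 M to 18.9 M fragments (M, 1e6) per library, a spread of 5.6%. At 1 FPKM a transcript of 2000 nt had a counting SD of 16.7%, for counting error only. Gene models under 200 nt, 953 of those tested, took 27.5% to 31.1% of the total FPKM of a library. The share was 27.5% to 29.0% in KO, 28.3% to 29.4% in WT and 29.5% to 31.1% in K262Q.

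The fit used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(FPKM + 1), with all 9 samples in 1 fit of 3 groups, genes with a mean of at least 1 FPKM, two-sided tests, Benjamini-Hochberg adjustment over 12212 genes and a threshold of 0.05. Errors of fold changes are SE and those of FPKM are SD. An exact permutation test of 3 against 3 cannot give a p under 0.1. Comparisons were K262Q against WT, WT against KO and K262Q against KO. Genes shared by both rescues were counted and compared with 100 simulations of all 9 samples without any change. In these, both rescues were set against the same simulated KO group, and noise was normal with the spread of each gene within groups.

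Before the data were examined, 29 gene sets were written down, Cd274 alone being 1 of them, and 22 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with adjustment over 66 tests. Camera with an estimated correlation and fry, which tests whether genes of a set move on balance in 1 direction without comparing it with other genes, were run beside it. Members matched by symbol (779) or by synonym (3), and 1 was not matched. A list of YAP and TEAD targets and a list of BMP-SMAD targets were added later.

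Named genes followed a rule fixed at the same time: Cd274, then among genes past the threshold with groups that do not overlap and a higher mean of at least 2 FPKM, the 8 largest rises and 8 largest falls of the main comparison and the 6 largest of the others each way, leaving out models without a proper name. In each list up to 3 members with the smallest adjusted p were named. Exceptions are stated where they occur.

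The method was tested on simulated data with 200 changed genes in each of 10 runs. It recovered 28.8%, 66.4%, 88.6% and 94.0% of genes changed 1.25-fold, 1.5-fold, 2-fold and 3-fold, with 5.6% false among calls. The changed genes were drawn only from those with a mean above 2 on the log2(FPKM + 1) scale. Noise was normal, and recovery of lower genes was not measured. Of 20 lists of 30 genes moved by 0.3 on the log2 scale 20 were found, and 0 of 200 unmoved lists were called. Simulated genes varied independently of each other, so these lists do not test camera on members that vary together. In the data the estimated correlation ran from -0.025 in the checkpoint list to 0.814 in the mitochondrially encoded list, with 0.414 in the interferon list.

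Alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, upper-quartile scaling, TMM scaling factors computed in R code, only the 2 groups compared, no trend, the replicate number as a block, each library left out in turn and a 1.5-fold minimum. Leaving out gene models under 200 nt was added after the data were seen. Numbers gave no clear pairing: deviations of same-number samples correlated by -0.036 to 0.078, against -0.074 to 0.051 for other numbers. Between WT and K262Q the same-number values were 0.078, 0.035 and 0.028, and the others lay between -0.074 and 0.042. A weak pairing of these 2 groups is therefore not excluded. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9. Raw reads were not analysed here, so vector sequence, the K262Q codon and strand were not examined.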

Results

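RNA was sequenced from 9 samples of CT26, a mouse colorectal carcinoma line, in which Pd-l1 had been knocked out and a retroviral vector then added back. Pd-l1 (gene symbol Cd274) encodes the ligand through which tumour cells engage the PD-1 receptor on T cells. The vector was empty (KO), carried wild-type mouse Pd-l1 (WT), or carried the K262Q form (K262Q), in which a lysine of the cytoplasmic tail is replaced by glutamine, a change often used to mimic an acetylated lysine. Each of the 3 groups had 3 samples, and per the labels each group was a puromycin-selected polyclonal line. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The values are the deposited FPKM (fragments per kilobase of transcript, scaled to library size). The table lists 53796 genes, of which 26417 were listed at 0 in every sample. A mean of at least 1 FPKM was reached by 12212 genes, and these were tested. Folds below are those of the fit, on FPKM + 1, and so are smaller than ratios of the means for genes of low level. Read counts are not part of the table, but the spacing of low values implied 17.9 M to 18.9 M fragments (M, 1e6) per library, so that 1 FPKM of a 2000 nt transcript stood for 35.8 to 37.8 fragments. The number of genes above 0 was 20472 in KO replicate 1 and between 19296 and 19684 in the other libraries.

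Cd274 transcript separated the empty-vector cells from both rescued lines. Cd274 (ENSMUSG00000016496; chromosome 19, 29367455 to 29388095, GRCm38) measured 0.982, 0.357 and 0.791 FPKM in KO replicates 1, 2 and 3, against 36.3 ± 1.45 FPKM in WT and 39.7 ± 1.90 FPKM in K262Q (SD, n = 3). The rise over KO was 4.47 ± 0.13 on the log2(FPKM + 1) scale in WT (SE, limma, Benjamini-Hochberg adjusted p = 5.79e-06) and 4.59 ± 0.13 in K262Q (adjusted p = 3.14e-06). Between K262Q and WT the difference was 0.12 ± 0.13 (adjusted p = 0.575). This SE pools the spread of all 3 groups, the KO libraries near 0 included, and is not that of the 2 rescues alone. Replicates 1, 2 and 3 measured 35.6, 35.4 and 38 FPKM in WT and 37.6, 41.3 and 40.1 FPKM in K262Q. The lowest K262Q value lay just below the highest WT value. The rescue transcript comes from the vector, while the values are assigned to the Cd274 gene, and protein was not measured here.

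**Figure D1:**
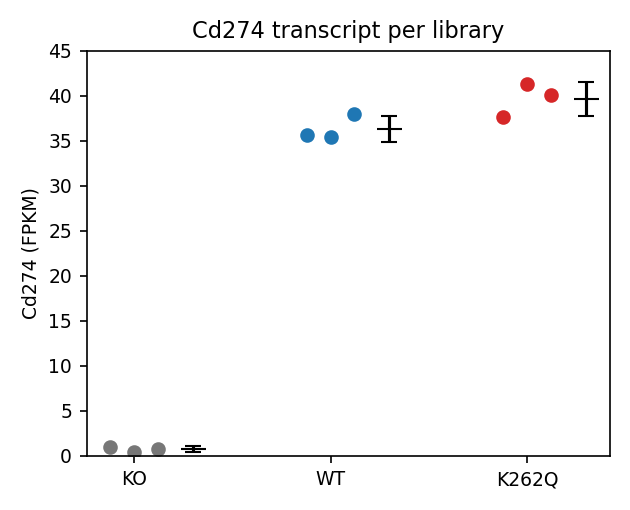
Cd274 in FPKM (vertical axis) in each library of the KO, WT and K262Q groups; points are the 3 libraries of a group, and the black bar beside them is the mean with its SD. KO libraries lie between 0.357 and 0.982 FPKM, while both rescued groups average 36.3 and 39.7 FPKM.

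The main comparison, K262Q against WT, asks what the substitution changes when Pd-l1 is present at a similar transcript level. In K262Q cells the Id genes rose together: Id3 was 4.42-fold higher (13.1 ± 2.87 against 2.15 ± 0.258 FPKM, adjusted p = 0.00691), Id1 2.48-fold (31.0 ± 4.37 against 11.9 ± 1.03 FPKM, adjusted p = 0.00522) and Id2 2.10-fold (36.3 ± 2.71 against 16.9 ± 2.06 FPKM, adjusted p = 0.0105). The Id proteins are dominant-negative partners of basic helix-loop-helix transcription factors. Rises passed the threshold in 15 of 22 genes of sterol synthesis, 12 of 32 of DNA replication, 9 of 30 of mitosis and 10 of 23 of the unfolded protein response, and falls in 7 of 31 of the hypoxia response, 10 of 30 of the ATF4 response and 6 of 56 of the interferon response. All 7 lists were called by camera at the preset correlation, and each had adjusted p = 0.365 with an estimated correlation. By the naming rule, the largest falls were in the p53 target Gadd45a (4.50-fold lower, adjusted p = 0.0432), Car9, a carbonic anhydrase induced by hypoxia (4.03-fold lower, adjusted p = 0.0241), and Egr1, an immediate early transcription factor (3.39-fold lower, adjusted p = 0.041). With 1 library left out, Id1 and Id3 kept their call in all 9 fits and Id2 lost it in 2, while Gadd45a and Egr1 lost it in 7 and Car9 in 6.

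The other largest rises by the naming rule were in U90926 (2.92-fold), Dlk2 (1.96-fold), Rpl26 (1.85-fold), Sapcd2 (1.77-fold) and the homeobox gene Prrx2 (1.67-fold, 124 ± 6.92 against 74.1 ± 3.13 FPKM, adjusted p = 0.00522). The other largest such falls were in Arid5a (2.84-fold), the ATF4 target Trib3 (2.71-fold), Tcim (2.49-fold), Txnip, an inhibitor of thioredoxin (2.46-fold), and Chac1, a glutathione-degrading enzyme induced by ATF4 (2.40-fold). Id1 lies on chromosome 2 (152736251 to 152737410), Id2 on chromosome 12 (25093799 to 25097140), Id3 on chromosome 4 (136143497 to 136145755), Gadd45a on chromosome 6 (67035096 to 67037457) and Car9 on chromosome 4 (43506966 to 43513729), all in GRCm38. Rpl26 has near-identical pseudogene copies, so its value is uncertain.

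**Figure D2:**
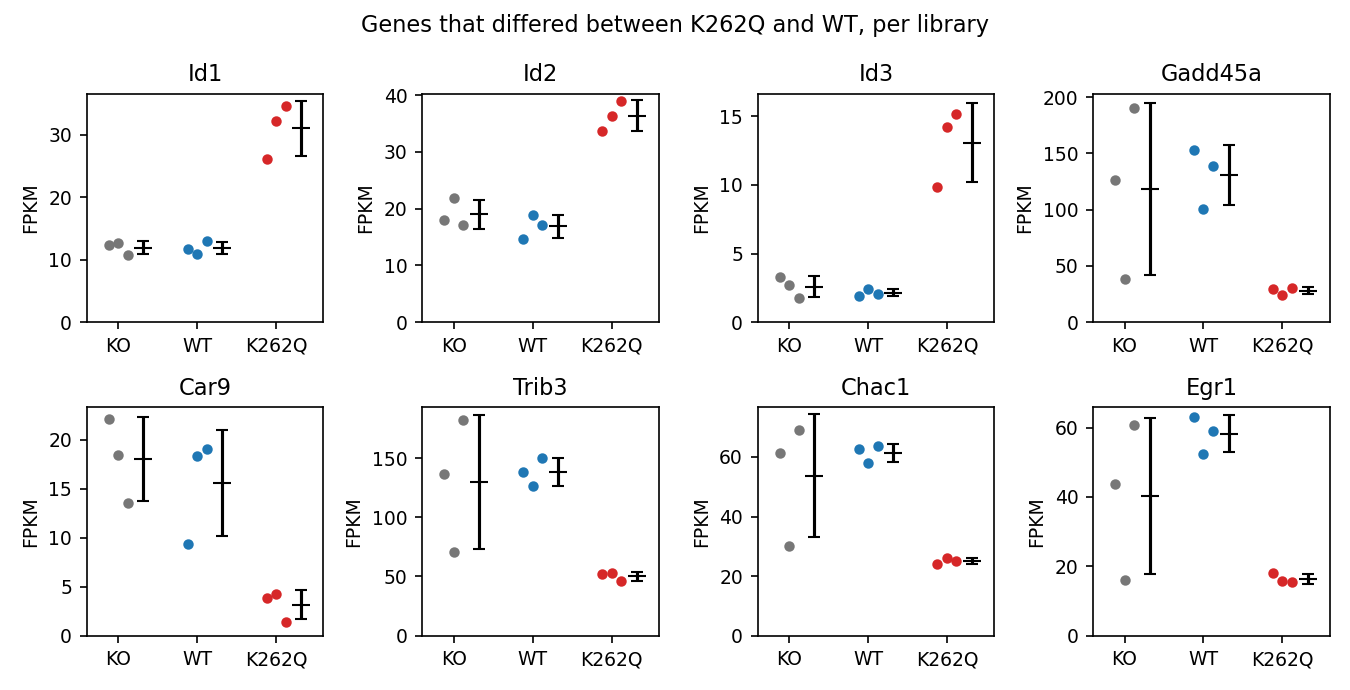
FPKM (vertical axis, from 0) of 8 genes that differed between K262Q and WT, in each library of the 3 groups; points are libraries and the black bar beside them is the mean with its SD. Id1, Id2 and Id3 are higher in all 3 K262Q libraries than in the other 6, while the KO values of Gadd45a spread from 38.0 to 190 FPKM.

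In all, 1145 genes differed between K262Q and WT (limma, Benjamini-Hochberg adjusted p under 0.05), 776 higher and 369 lower in K262Q, or 67.8% higher. That share depended on scaling: it was 43.4% higher of 931 genes after upper-quartile scaling and 57.1% higher of 1064 after TMM scaling. Total FPKM outside gene models under 200 nt was 495637 to 513248 in K262Q libraries and 467425 to 483010 in WT libraries. Whether this difference in total adds to the rises was not tested. Most changes were small, with a median size of 0.34 on the log2 scale. At least 1.5-fold changes were seen in 142 genes, 47 higher and 95 lower in K262Q, so falls outnumbered rises among them. At least 2-fold changes were seen in 39. The groups did not overlap in 35.4% of tested genes, where chance gives 10%. The count fell to 29 without K262Q replicate 2, 41 without K262Q replicate 3, 44 without WT replicate 2, 49 without WT replicate 1, 333 without K262Q replicate 1, 371 without WT replicate 3 and 718 without KO replicate 1. It was 1597 without KO replicate 2.

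Metabolic and growth lists moved upward in K262Q. Of 22 cholesterol biosynthesis genes, 15 rose, 0 fell and 7 did not pass (21 rose adjusted over the list alone), with a list mean of 0.37 (camera adjusted p = 1.54e-10; adjusted p = 0.365 with an estimated correlation). Acat2 rose 1.53-fold, Fdft1, the squalene synthase, 1.46-fold and Msmo1 1.29-fold. Of 15 fatty acid synthesis genes, 3 rose (7 adjusted over the list alone), including Fasn at 1.39-fold and Elovl6 at 1.37-fold (camera adjusted p = 0.0389; adjusted p = 0.365 with an estimated correlation). This list lost its call after upper-quartile and after TMM scaling. Of 29 nuclear oxidative phosphorylation genes, 5 rose (5 adjusted over the list alone), with Ndufa4 at 1.24-fold (camera adjusted p = 0.000171; adjusted p = 0.365 with an estimated correlation). Among 22 NRF2 targets, 5 rose, 1 fell and 16 did not pass (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00169; adjusted p = 0.365 with an estimated correlation). Gclm, a subunit of the glutathione-synthesising ligase, rose 1.38-fold, while the cystine transporter Slc7a11, which is also an ATF4 target, fell 1.61-fold.

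Proliferation lists were higher as well. Of 32 DNA replication and E2F targets, 12 rose and 0 fell (17 rose adjusted over the list alone), with a mean of 0.27 (camera adjusted p = 3.87e-09; adjusted p = 0.365 with an estimated correlation). Mcm5, part of the replicative helicase, rose 1.29-fold and Lig1 1.24-fold. Of 30 mitotic genes, 9 rose and 0 fell (16 rose adjusted over the list alone), with Ccnb1, the mitotic cyclin, at 1.48-fold and Ccna2 at 1.35-fold (camera adjusted p = 4.22e-06; adjusted p = 0.365 with an estimated correlation). Among 30 DNA repair genes only Atm rose, 1.38-fold, and 29 did not pass (0 adjusted over the list alone; camera adjusted p = 0.0401; adjusted p = 0.365 with an estimated correlation). The 34 cytosolic ribosomal protein genes had 8 rises and 0 falls (15 rises adjusted over the list alone), with Rpl5 at 1.40-fold (camera adjusted p = 4.24e-06; adjusted p = 0.365 with an estimated correlation). Ribosomal protein genes have many pseudogene copies that can share their reads.

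Chaperone lists rose too. In the list of the endoplasmic reticulum unfolded protein response, 10 of 23 genes rose, 0 fell and 13 did not pass (12 rose and 1 fell adjusted over the list alone), with a mean of 0.23 (camera adjusted p = 2.67e-05; adjusted p = 0.365 with an estimated correlation). Creld2 rose 1.53-fold, Manf 1.46-fold and Pdia3 1.24-fold, all of them proteins of the endoplasmic reticulum. Of 13 heat shock genes, 6 rose (8 adjusted over the list alone), with the chaperone Hspa8 at 1.38-fold (camera adjusted p = 0.000551; adjusted p = 0.365 with an estimated correlation).

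Stress and hypoxia lists moved downward in K262Q. Of 30 ATF4 and amino acid response genes, 10 fell, 1 rose and 19 did not pass (14 fell and 2 rose adjusted over the list alone), with a mean of -0.39 (camera adjusted p = 6.64e-07; adjusted p = 0.365 with an estimated correlation). Nupr1 fell 2.16-fold, and the largest falls named above include the members Trib3 and Chac1. Of 31 glycolysis and hypoxia response genes, 7 fell and 24 did not pass (13 fell adjusted over the list alone), with a mean of -0.30 (camera adjusted p = 3.62e-06; adjusted p = 0.365 with an estimated correlation). Ndrg1 fell 2.12-fold, the oxidoreductase Ero1l 1.71-fold and the angiogenic factor Vegfa 1.56-fold; the other members that fell were Car9, Bnip3, P4ha2 and Ddit4, and no glycolytic enzyme passed. Of 19 immediate early genes, 3 fell (7 adjusted over the list alone), namely Egr1, Klf6 (1.61-fold) and Maff (1.41-fold; camera adjusted p = 9.95e-06; adjusted p = 0.365 with an estimated correlation). Of 23 matrix and mesenchymal genes, 3 fell (3 adjusted over the list alone): Snai2 2.18-fold, fibronectin (Fn1) 1.49-fold and Zeb2 1.47-fold (camera adjusted p = 0.04; adjusted p = 0.365 with an estimated correlation).

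Of 56 interferon response genes, 6 fell, 1 rose and 49 did not pass (14 fell and 1 rose adjusted over the list alone), with a mean of -0.24 (camera adjusted p = 1.38e-09; adjusted p = 0.365 with an estimated correlation). Psmb8, an immunoproteasome subunit, fell 1.43-fold and Uba7 1.69-fold, while Socs1, an inhibitor of cytokine signalling, rose 1.35-fold. Of 25 MHC class I genes, 4 fell and 4 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.365 with an estimated correlation). B2m, the shared light chain, fell 1.19-fold, whereas the chaperones Canx (1.20-fold) and Pdia3 rose. Of 26 NF-kB genes, 2 fell and 2 rose (3 and 2 adjusted over the list alone), with Tnfrsf9 2.34-fold lower and Vcam1 1.18-fold higher (camera adjusted p = 0.00151; adjusted p = 0.365 with an estimated correlation). Of 15 cytokine genes, Vegfa and Tgfb3 (1.32-fold) fell and 13 did not pass (4 fell adjusted over the list alone; camera adjusted p = 0.00292; adjusted p = 0.365 with an estimated correlation).

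Checkpoint and related surface genes were not called as a list (camera adjusted p = 0.217), although Pvr, a ligand of TIGIT, fell 1.74-fold (38.5 ± 1.71 against 67.7 ± 3.30 FPKM, adjusted p = 0.016) and Cd80 fell 1.58-fold (adjusted p = 0.0468) among 11 tested members (2 fell and 1 rose adjusted over the list alone). The p53 list was not called (camera adjusted p = 0.515): 4 of 23 members rose, including Bax at 1.24-fold and Trp53 itself at 1.27-fold, and 4 fell (7 and 6 adjusted over the list alone), and its mean of -0.13 went against fry's upward direction. Neither the mitochondrially encoded genes (1 of 9 rose, mt-Rnr2 at 1.47-fold; 3 adjusted over the list alone; camera adjusted p = 0.442) nor the machinery of PD-L1 acetylation, endocytosis and nuclear import (1 of 28 rose, Kpnb1 at 1.17-fold; 1 adjusted over the list alone; camera adjusted p = 0.132) was called.

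The 18 called lists came from 22 tested in each comparison, with adjustment over all 66 tests; 0 of the 18 were called with an estimated correlation and 10 were called by fry, all of them lists that were higher in K262Q; none of the 8 lower lists was called by fry. Library KO replicate 2 lay on the K262Q side of the mean of the other KO libraries in 17 of the 18 lists, the hypoxia list being the exception. Among single genes, Gadd45a measured 126.8, 38.0 and 190 FPKM in KO replicates 1, 2 and 3, and Trib3 136.5, 70.5 and 182.6 FPKM.

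**Figure D3:**
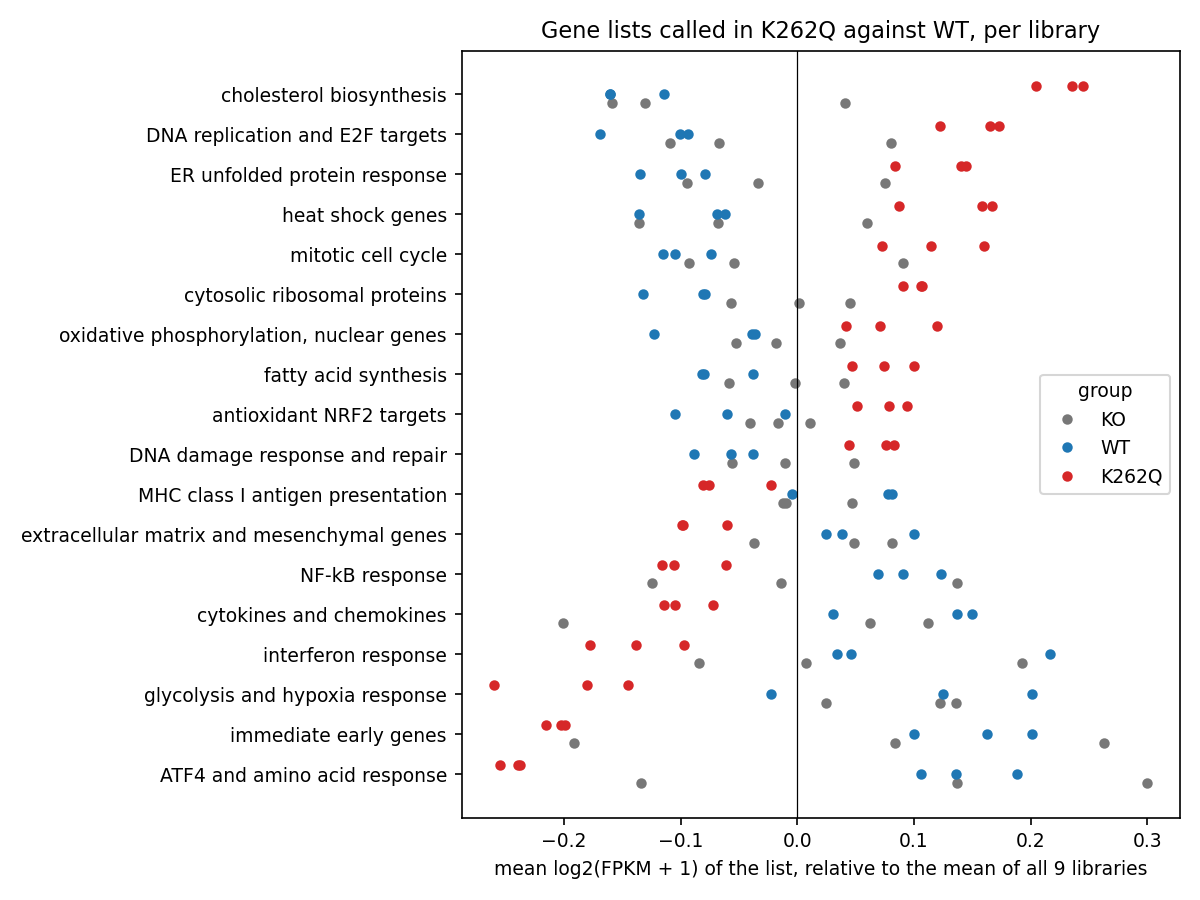
Mean log2(FPKM + 1) of each of the 18 gene lists called in K262Q against WT, relative to the mean of all 9 libraries (horizontal axis), with 1 point per library and a colour per group. K262Q libraries lie apart from WT libraries in every list shown, and the KO libraries spread more widely in the stress lists, with a range of 0.434 in the ATF4 list.

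Restoring wild-type Pd-l1, WT against KO, asks what Pd-l1 itself changes in these cells, and few genes passed the test. Cd274 rose, as given above. Coq4, a coenzyme Q synthesis gene, fell 1.70-fold (17.8 ± 2.02 against 30.8 ± 2.18 FPKM, adjusted p = 0.0291). In total 10 genes differed (limma, adjusted p under 0.05), 6 higher and 4 lower, with 686 genes at an unadjusted p under 0.05. Of the 10, 7 are gene models outside the naming rule and are named after their values were seen. BC055324 fell to 10.98 ± 0.423 from 18.4 ± 0.442 FPKM and Gm17067 rose to 14.4 ± 2.89 from 1.83 ± 0.326 FPKM. 2900060B14Rik, a 616 nt antisense transcript inside Clasp1, measured 105.3 ± 50.9 FPKM in WT, 1.03 ± 0.483 in KO and 0.269 ± 0.0233 in K262Q. Without stated strand its reads cannot be told from those of Clasp1, and the short model Gm22710 lies inside 2900060B14Rik on the same strand. Mir3062, Gm25604, Snord43 and Gm25291 are shorter than 200 nt and were listed at 0 in every library of a group, and their values above 0 were all 1 or 2 times the smallest one. The limma count reached 18 without WT replicate 3, and Coq4 lost its call in 7 of the 9 fits that left out a library. Coq4 also lost it with the replicate block and with only the 2 groups compared.

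Lists moved little between WT and KO: 11 of 22 were called by camera, 5 higher and 6 lower in WT, 0 with an estimated correlation and 0 by fry. No list had a member past the threshold over all genes; adjusted over the list alone, 1 MHC class I and 2 fatty acid synthesis genes were lower and 0 passed in the other 20 lists. The ribosomal (mean -0.09, camera adjusted p = 1.13e-05), E2F (-0.09, 0.000275), unfolded protein (-0.09, 0.000659), mitotic (-0.08, 0.000995), oxidative phosphorylation (-0.05, 0.0153) and cholesterol lists (-0.06, 0.0334) were lower in WT. With an estimated correlation, adjusted p was 0.365 for the ribosomal, E2F and unfolded protein lists, 0.382 for the mitotic, 0.418 for the oxidative phosphorylation and 0.478 for the cholesterol list. The NF-kB (mean 0.10, camera adjusted p = 0.000878), interferon (0.06, 0.00101), immediate early (0.10, 0.00254), cytokine (0.12, 0.00273) and p53 lists (0.07, 0.0189) were higher in WT. Here the adjusted p was 0.478 for the interferon list and 0.365 for the other 4 with an estimated correlation. Only 2 of the lists were called without KO replicate 2, against 17 without KO replicate 3. Not called were the MHC class I (camera adjusted p = 0.0579), fatty acid (0.0644), mitochondrially encoded (0.0644), NRF2 (0.0889), DNA repair (0.192), heat shock (0.215), matrix (0.218), hypoxia (0.245), ATF4 (0.491), checkpoint (0.522) and PD-L1 machinery lists (0.94). Mean and median differed in sign in the hypoxia (0.007 and -0.004) and ATF4 lists (0.042 and -0.004).

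Restoring the mutant, K262Q against KO, asks what the substituted protein changes relative to cells without Pd-l1. The Id genes rose here too, Id3 3.92-fold (adjusted p = 0.0152), Id1 2.46-fold (adjusted p = 0.00902) and Id2 1.87-fold (adjusted p = 0.0292). Id1 kept its call with each library left out, while Id3 lost it in 2 and Id2 in 7 of the 9 such fits, and Car9, below, in 8. Besides Cd274, all 20 genes named in this comparison by the rule lost their call with the replicate block and with only the 2 groups compared. U90926 (2.80-fold), Dlk2 (1.66-fold) and the mitochondrial tRNA model mt-Ts2 (3.84-fold) rose as well. The mt-Ts2 model is 59 nt long, its values are not all whole multiples of the smallest one, and its number of fragments was not determined. Car9 fell 4.74-fold (adjusted p = 0.0452), Tcim by 1.14 on the log2 scale, Ndrg1 1.84-fold, Creb5 1.84-fold, Ero1l 1.81-fold and Gtpbp2 1.80-fold.

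Of the 154 genes (limma, adjusted p under 0.05), 88 were higher and 66 lower in K262Q, or 57.1% higher, against 43.6% of 234 after upper-quartile scaling. The count was 1117 without KO replicate 2, 14 without KO replicate 1 and 22 without KO replicate 3. It was 51, 14 and 26 without WT replicates 1, 2 and 3, and 17, 14 and 13 without K262Q replicates 1, 2 and 3. It was 10 when only the 2 groups compared were fitted, 37 without the trend and 297 after TMM scaling. Between this comparison and K262Q against WT, 138 genes were called in the same direction; both use the same K262Q libraries, so overlap arises without any change, and 80.4% of all genes shared their sign.

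By camera 12 of 22 lists were called in K262Q against KO, 8 higher and 4 lower, 0 with an estimated correlation and 2 by fry. Cholesterol biosynthesis was higher by 0.31 (1 of 22 rose, Acat2 at 1.42-fold; 20 adjusted over the list alone; camera adjusted p = 8.98e-11; adjusted p = 0.365 with an estimated correlation). Higher too were the E2F (mean 0.19, camera adjusted p = 1.51e-06; 1 rose, E2f1 by 0.32, and 9 adjusted over the list alone), heat shock (0.19, 0.00031), mitotic (0.13, 0.000445), unfolded protein (0.14, 0.000719; 1 rose, Creld2 at 1.35-fold, and 11 rose and 2 fell adjusted over the list alone), NRF2 (0.09, 0.0054; 1 rose, Gclm at 1.27-fold, and 4 rose and 1 fell adjusted over the list alone), oxidative phosphorylation (0.09, 0.0054) and ribosomal lists (0.11, 0.00956). Adjusted p was 0.382 for oxidative phosphorylation and 0.365 for the other 6 with an estimated correlation. The ATF4 (mean -0.34, camera adjusted p = 7.73e-08; 0 of 30 passed, 12 fell adjusted over the list alone), interferon (-0.18, 7.55e-07; 0 of 56 passed), hypoxia (-0.29, 4.34e-06; 4 of 31 fell, 11 adjusted over the list alone) and immediate early lists (-0.26, 0.00258; 0 of 19 passed) were lower. All 4 had adjusted p = 0.365 with an estimated correlation. Outside called lists, Pvr fell 1.58-fold (adjusted p = 0.0431), Fn1 1.44-fold (adjusted p = 0.0373), Krt18 1.28-fold (adjusted p = 0.036) and Lck 1.57-fold (adjusted p = 0.0495). Not called were the MHC class I (camera adjusted p = 0.0867), matrix (0.106), PD-L1 machinery (0.119), cytokine (0.122), NF-kB (0.128), DNA repair (0.128), fatty acid (0.13), checkpoint (0.218), p53 (0.383) and mitochondrially encoded lists (0.901). Mean and median differed in sign in the p53 (-0.061 and 0.072) and mitochondrially encoded lists (0.052 and -0.052).

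The 2 rescues shared 4 genes in the same direction against KO: Cd274, Snord43, Gm25604 and Mir3062, the last 3 being models under 200 nt with values of 1 or 2 times the smallest one. Both comparisons use the same KO libraries, and the shared count was 9, 11 and 8 without KO replicates 1, 2 and 3. Simulated unchanged groups with a simulated KO group in common shared 0.05 genes on average and at most 1 in 100 runs. Independent lists would share 0.043 higher and 0.022 lower genes. The simulation drew normal noise, which does not reproduce values that move in steps of the smallest one. For the 3 short models it is therefore no measure of how often such sharing arises. Across genes the covariance of the fold changes was 0.115, against a simulated mean of 0.0853 (0.0653 to 0.102), and the correlation was 0.423, against 0.499 simulated. The simulated rescues also had their KO group in common, so shared controls are already part of the simulated covariance. With 3 KO libraries the real controls could not be split. Noise in the simulation was normal and without steps for all 12212 tested genes, the 953 models under 200 nt included. The simulated range is therefore no strict chance range, and no conclusion is drawn from the difference in covariance.

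Lists with under 5 tested members give values only. Of 12 MHC class II genes 2 were tested, and Ifi30 rose 1.24-fold in K262Q against WT while H2-Ab1 was listed at 0 in every group. Of 23 epithelial genes 4 were tested; Krt18 measured 34.9 ± 0.713 FPKM in KO, and Epcam and Cdh1 were at or near 0. Of 27 replication-dependent histone genes 3 were tested, with Hist1h1c at 3.23 ± 0.349 FPKM in K262Q against 3.25 ± 0.248 in WT. Most markers of other cell types were too low to test. Of 17 macrophage markers 2 were tested: Cd68 measured 2.93 ± 0.5 FPKM in WT, and Cd14 measured 49.3 ± 1.68 FPKM in WT and 57.4 ± 0.946 in K262Q, a 1.16-fold rise. Also tested were, of 17 lymphocyte markers, only Lck (11.3 ± 1.84 FPKM in KO, 9.61 ± 0.994 in WT and 6.76 ± 0.133 in K262Q), and of 12 endothelial and pericyte markers only Pdgfrb (2.91 ± 0.338 FPKM in K262Q and 3.28 ± 0.266 in WT). Ptprc averaged 0.00756 FPKM in KO, 0 in WT and 0.00773 in K262Q.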

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

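The tests of splits, of culture state, of Cd274 amount and of short gene models were chosen after the results were seen, whereas the test of YAP and TEAD targets was written before its result. The mean effects of the K262Q rescue and of the WT rescue, both against KO, had opposite signs in all 22 tested lists, since KO lay between the rescues. The 8 lists below are those that camera called in both rescues, in opposite directions, and whose difference it also called in K262Q against WT. All 8 differences have adjusted p = 0.365 with an estimated correlation.

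The cholesterol list differed by 0.37 on the log2 scale (-0.06 in WT and 0.31 in K262Q, adjusted p = 1.54e-10). The DNA replication and E2F list differed by 0.27 (-0.09 and 0.19, adjusted p = 3.87e-09) and the mitotic list by 0.21 (-0.08 and 0.13, adjusted p = 4.22e-06). The unfolded protein list differed by 0.23 (-0.09 and 0.14, adjusted p = 2.67e-05), ribosomal proteins by 0.20 (-0.09 and 0.11, adjusted p = 4.24e-06) and oxidative phosphorylation by 0.14 (-0.05 and 0.09, adjusted p = 0.000171). The interferon list differed by -0.24 (0.06 and -0.18, adjusted p = 1.38e-09) and immediate early genes by -0.36 (0.10 and -0.26, adjusted p = 9.95e-06). The WT effects are small, and 7 of the 8 lost their call without KO replicate 2, where the cholesterol mean was -0.000392 and the immediate early mean -0.0186; the ribosomal list kept its call.

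The amount of Cd274 transcript was tested first for the lists that differ between K262Q and WT. Restoring it to 36.3 FPKM in WT changed 9 other genes, against 1145 between K262Q and WT, where Cd274 differed by 0.12 ± 0.13. These values argue against transcript amount as the whole cause. The K262Q protein itself remains among the open explanations, and it was not tested apart from the line that carries it.

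A culture state that varies between samples may contribute. In 5 of the 18 called lists (interferon, NF-kB, cytokines, ATF4 and immediate early genes) the range over the 3 KO libraries was at least as wide as the gap between K262Q and WT. The range over the WT libraries reached the gap in 0 of the 18 lists, and that over the K262Q libraries in 0. KO replicate 2 lay toward K262Q, relative to the mean of the other KO libraries, in 17 of 18 lists and in 82.4% of the 1145 genes. For KO replicates 1 and 3 the shares were 28.4% and 27.2%. The 3 deviations of a gene cancel, so these low shares follow in part from that of KO replicate 2. For the other 13 lists the KO range stayed below the gap; each group is 1 line, so a state of that line and an effect of K262Q cannot be told apart. A lower cell density at harvest in K262Q would raise YAP and TEAD targets. The 19 tested ones changed by -0.11 on average, in the other direction (95% interval over genes -0.23 to 0.01; 11 negative), so the list gave no sign of lower density, though the interval does not exclude 0.

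Calls on gene models under 200 nt were weighed as well. Of 16 such models called in any comparison, 11 had at most 3 fragments in every library, taking whole multiples within 0.03 of the smallest value as fragments. That the smallest value stands for 1 fragment was assumed, and was not checked for each model. For these, single fragments scaled up by the short length are a candidate explanation. Gm22980, with 1 step in each K262Q library and 0 elsewhere, was listed at 150 ± 2.06 FPKM in K262Q and had the smallest adjusted p of that comparison, 3.56e-10. For the other 5 a difference in short RNAs remains open, and no biological explanation was tested.

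Regrouping the 6 samples of a comparison gives 10 splits, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, reached the real count. K262Q against WT gave 1145 genes and at most 5 in another split, WT against KO 10 and at most 5, and K262Q against KO 154 and at most 6.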

How the results depend on the processing

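Leaving out gene models under 200 nt was chosen after the data were seen; the other settings were planned. Cd274 kept its calls in each setting run for it, at 4.31 to 4.58 for WT and 4.43 to 4.70 for K262Q against KO when 1 library was left out, and 0.09 to 0.16 between them. For Cd274 these settings did not include the fit of only the 2 groups compared. In K262Q against WT upper-quartile scaling kept 770 of the 1145 calls. Id1, Id3 and Prrx2 kept their K262Q against WT call in 18 of 18 settings, Id2 in 16, Gadd45a in 9, Car9 in 11 and Egr1 in 8. In K262Q against KO all 20 genes named by the rule besides Cd274 lost their call with the replicate block and with only the 2 groups compared, and 14 of them without the trend and 14 with no filter.

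The count for K262Q against WT, 1145, was 353 with no filter and 142 at 1.5-fold or more, and 29 (without K262Q replicate 2) to 1597 (without KO replicate 2) with 1 library left out. WT against KO, 10, gave 18 with no filter, 6 with the replicate block, 6 without short models and 9 to 18 with 1 library left out. K262Q against KO, 154, gave 55 with no filter, 234 and 297 with upper-quartile and TMM scaling, 10 with only the 2 groups, 37 with no trend, 5 with the block, 329 without short models, 40 at 1.5-fold or more, and 13 (without K262Q replicate 3) to 1117 (without KO replicate 2). Genes shared by the rescues, 4, were 10 with no filter, 2 without short models and 4 to 11 with 1 library left out. A left-out library leaves 2 in its group, and no filter tests more genes. A library of the group outside a comparison enters its count only through the spread, which the fit estimates over all 3 groups. For K262Q against WT these are the KO libraries, and the fit of only the 2 groups compared gave 1382. The cause was not tested for the other settings.

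With an estimated correlation 0, 0 and 0 lists were called in K262Q against WT, WT against KO and K262Q against KO, and with fry 10, 0 and 2, in place of 18, 11 and 12. With 1 library left out the calls were 16 to 18, 2 (without KO replicate 2) to 17 (without KO replicate 3), and 11 to 15. In WT against KO the signed test of 2 lists reversed without KO replicate 2, at means of -0.000392 (cholesterol, from -0.1 without KO replicate 3) and -0.0186 (immediate early genes, up to 0.209 without KO replicate 3); the cause was not tested. The alternative for counts was not run, since the table holds no counts. Depth limits genes near 1 FPKM, where a 2000 nt transcript has 35.8 to 37.8 fragments.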

Other observations

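The test of BMP targets was written before its result was seen, while the genes below were singled out after theirs. Id1, Id2 and Id3 are known targets of BMP-SMAD signalling, and all 3 were higher in each K262Q library than in each WT library, so higher BMP-SMAD signalling in K262Q cells was tested as a hypothesis. The 10 other tested BMP-SMAD targets changed by -0.05 on average on the log2 scale (95% interval over genes -0.22 to 0.12), with 4 positive and 6 negative, and 0 passed the threshold. The list gave no sign of such signalling, but 10 targets that go both ways may not exclude it. Over KO replicates 1, 2 and 3, Id1 measured 12.35, 12.75 and 10.71 FPKM, Id2 17.93, 21.93 and 17.11 FPKM and Id3 3.32, 2.68 and 1.79 FPKM.

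2900060B14Rik measured 105.3 ± 50.9 FPKM in WT, 1.03 ± 0.483 in KO and 0.269 ± 0.0233 in K262Q. It lies at chromosome 1, 118458652 to 118459267 in GRCm38, antisense inside Clasp1. Clasp1 itself changed by -0.03 between WT and KO on the log2 scale, Tsn by -0.02 and Nifk by -0.02. Gm22710, a short model inside 2900060B14Rik on the same strand, changed by 0.61 between WT and KO and by 0.66 between K262Q and WT. It was not called in WT against KO.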
